A study of Drosophila melanogaster with 3 samples.

How the data were processed

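TF ChIP-seq with an anti-GFP antibody was run on whole embryos expressing GFP-tagged CG4820, in 3 biological replicates that the labels number 1 to 3. Each replicate came with a list of candidate peaks per genome build, and the series with a pooled candidate list and an optimal list. Per the deposited README files, each replicate's list was derived from that replicate's alignment and a control file, the pooled list from the alignments of all 3 replicates and the control, and the optimal list from these 4 lists by the irreproducible discovery rate (IDR), which compares peak ranks between replicates. The control is not used here. The aligner, the peak caller and the IDR limit are not given in the sources used here. The signal values are the deposited enrichment of each peak on its own list's scale, so they were ranked within a list and never compared between lists. The −log10 q-value column deposited by the authors holds 1 value for all peaks of an optimal list and was not used to rank. Summit positions were taken from the deposited offset column.

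Depth could not be assessed, since no read totals are given, so no sampling error of the reads is included. Intervals on shares of peaks or genes are 95% Wilson or exact (Clopper-Pearson) intervals and cover counting error only, and where 0 genes were bound the upper limit is 3 divided by the number of genes. Peak width was the same for most of a list, 416 bp in 77.8% of the optimal peaks. In the optimal list 7 intervals occur again with another summit, and each summit was kept as a peak. No 2 replicate lists shared an interval with equal signal, so none is a copy of another. The replicates come from 1 fly line, as the labels give it, and p-values over peaks or genes describe these peaks and not a population of embryos.

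Gene models came from Ensembl BDGP6.54, release 115, and sequence from the RefSeq genome of the same assembly, on the arms 2L, 2R, 3L, 3R, 4 and X. All peaks of the 5 dm6 lists lie inside these arms, and 99.8% of 30593 annotated start codons read ATG in the sequence. Transposable elements and pseudogenes were left out, which left 17896 genes and 13945 protein-coding genes. The dm3 lists were used only for peak counts and overlaps within dm3, without converting coordinates.

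An optimal peak was supported by a replicate if it overlapped at least 1 bp of that replicate's 4876 highest-signal peaks. Chance was estimated by 1000 random placements of the peaks within their arms, with unmappable sequence left in. A promoter peak had its summit within 500 bp of a TSS. Gene lists with at least 5 genes were tested against the other protein-coding genes with Fisher's exact test, and some were drawn by symbol pattern, so a few members belong to other families. Motifs and words were sought on both strands within 50 bp to each side of the summit and in flank sequence of equal size at 300 bp, with positions counted by motif centre so that both windows offer the same number. Words had to be in at least 20 peaks, were chosen on odd-ranked peaks and tested on even-ranked ones. All these tests, the lists, the motifs and the alternatives listed first were fixed before the data were examined. Shares by annotated location, side of the TSS and signal class, motif counts compared between promoters and other places, and A+T content were added later. Adjusted p-values are Benjamini-Hochberg values with a limit of 0.05.

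The named peaks and genes follow a rule set at the same time. It takes the 25 highest-signal optimal peaks that every replicate supports, each by the gene with the nearest TSS, and up to 5 that not every replicate supports. It adds CG4820, and from each list the members with the highest promoter signal, up to 4 where the list passed and up to 2 otherwise.

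Alternatives were other overlap rules, promoter distances of 250 and 1000 bp, other windows and flanks, peak midpoints, subsets of peaks, other backgrounds, the dm3 lists, and leaving out each replicate in turn by requiring support in the other replicates only. A control in which each motif or word was set against itself read backwards was added after seeing the data. The steps were tested on simulated data with fixed seeds. At random positions neither motifs nor words passed against flanks, a motif put into windows was called without any other, and a raised gene list was called. Random positions were not given the higher A+T content of the real summits. The simulation therefore does not show how the tests against flanks behave under such a difference. Against reversed words, however, many word pairs passed at random positions, so that control finds sequence order present anywhere in the genome and was not used to name words. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.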

Results

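Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the protein of the fly gene CG4820 sits on the genome of Drosophila melanogaster embryos. The flies carried CG4820 with a green fluorescent protein (GFP) tag at its C-terminal end, and an antibody against GFP pulled down the tagged protein with its DNA. Whole embryos of both sexes, aged 0 to 16 h, gave 3 biological replicates of 1 group, so no treated or mutant group was compared. Chromatin was sheared by sonication to fragments of 200 to 800 bp. The measurement is a set of peaks, meant as regions with more sequenced fragments than the background. On the dm6 genome build the candidate lists held 26597 peaks for replicate 1, 27004 for replicate 2 and 26145 for replicate 3. The candidate list of the pooled replicates held 21656 peaks, and the authors' final reproducible list, called the optimal list, held 4876. The authors label the pooled candidate list as peaks and background, so a candidate that was not called need not be a weaker binding site. Sequencing depth is unknown, because the files give peaks and no read totals. The signal of a peak is the authors' own value and was used only to rank peaks within a list.

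The first comparison asked how far the 3 replicates gave the same binding sites. Of the 4876 optimal peaks, 3553 (72.9%) overlapped the 4876 highest-signal peaks of every replicate. Single replicates supported 88.5% ± 1.14 of the optimal peaks (SD, n = 3). Another 979 peaks were supported by 2 replicates, 334 by 1 and 10 by none. Nearly all, 4853 (99.5%), overlapped some candidate peak of every replicate. Under the cut at the 4876 highest-signal peaks, every replicate supported 99.3% of the 2438 optimal peaks of highest signal and 46.4% of the other 2438, a fall that the cut itself brings about in part, since weaker peaks lie nearer to it. Random placement of the peaks on the same chromosome arms gave 85.7 ± 9.12 supported peaks (SD over 1000 placements) and at most 117, with a one-sided p of 0.001, the smallest that 1000 placements can give. Spearman's rank correlation of replicate signal, computed across the 4876 peaks, was 0.835 between replicates 1 and 2, 0.790 between replicates 1 and 3, and 0.809 between replicates 2 and 3. Peaks are not independent replicates, and the optimal list was itself chosen for reproducibility, so neither measure describes an unselected list. Since that list was derived from these replicates' own lists, more overlap than under random placement was built in. The p against random placement is therefore no independent evidence of reproducibility.

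**Figure D1:**
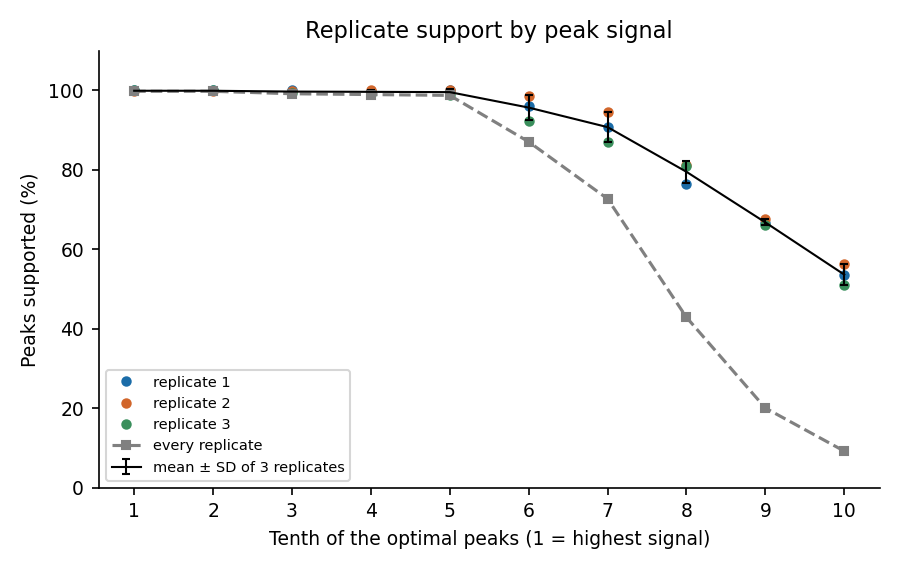
Percent of optimal peaks supported by each replicate's highest-signal peaks (vertical axis), in 10 classes of optimal peaks ordered by signal (horizontal axis, 1 the highest). Coloured points are replicates, the black line is their mean with its SD (n = 3), and the dashed line counts peaks that every replicate supports, which falls from 99.8% in class 1 to 9.24% in class 10.

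The 6 highest optimal peaks held ranks 1 to 6 in the same order in every replicate, while lower ones changed places, such as the peak nearest cbt with ranks 18, 19 and 10. The 25 optimal peaks of highest signal were supported by every replicate, and 20 of them had their summit within 500 bp of a transcription start site (TSS). The highest peak (dm6, chromosome arm 2L, 8162312 to 8163337, signal 11612.6) lay 139 bp upstream of Piezo (FBgn0264953), which encodes a mechanically gated ion channel, in intergenic sequence. It ranked 1 in all 3 replicates. Next came Eip75B, an ecdysone-induced nuclear receptor gene (FBgn0000568, 3L, 17999393 to 18000144, signal 10576.5, summit in the 5' UTR 68 bp downstream of a TSS), and CG7841 (FBgn0036502, 3L, 15508033 to 15508731, signal 8516.32, intergenic, 115 bp upstream). These ranked 2 and 3 in every replicate. CG44838 (FBgn0266101, 3L, 9461993 to 9462734, signal 6190.76) ranked 4 and CG11309 (FBgn0037070, 3L, 21304275 to 21304888, signal 5491.32) ranked 5 in each replicate, with summits in a 5' UTR and an intron.

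The other leading peaks lay at genes of varied kinds. Fdh, encoding formaldehyde dehydrogenase (3R, 10872224 to 10872886), had a signal of 3535.68. Hex-A, a hexokinase gene (X, 9585160 to 9585779), had 3331.78, and the carbonic anhydrase gene CAH3 (X, 8681106 to 8681701) had 3323.28. Taf4, encoding a subunit of the general transcription factor TFIID (3L, 16113374 to 16113927), had 2554.86, and Dp, the partner of E2F in cell cycle transcription (2R, 13223740 to 13224293), had 2433.24. The remaining peaks at promoters were nearest to CG13876, CG12316, Amun, CG14100, the UDP-galactose transporter gene Ugalt, CG31635, px, betaggt-I, the arginine methyltransferase gene Art3 and CG2921. The 5 leading peaks outside promoters were nearest to DNAlig3 (1292 bp from its TSS), the kinase gene Raf (3726 bp, in an intron), cbt (1369 bp), CG9135 (520 bp, with a summit within 100 bp in 2 replicates) and CG11050 (1033 bp). Signals of the 25 peaks ended at 2124.13, against a median of 171 over the optimal list.

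**Figure D2:**
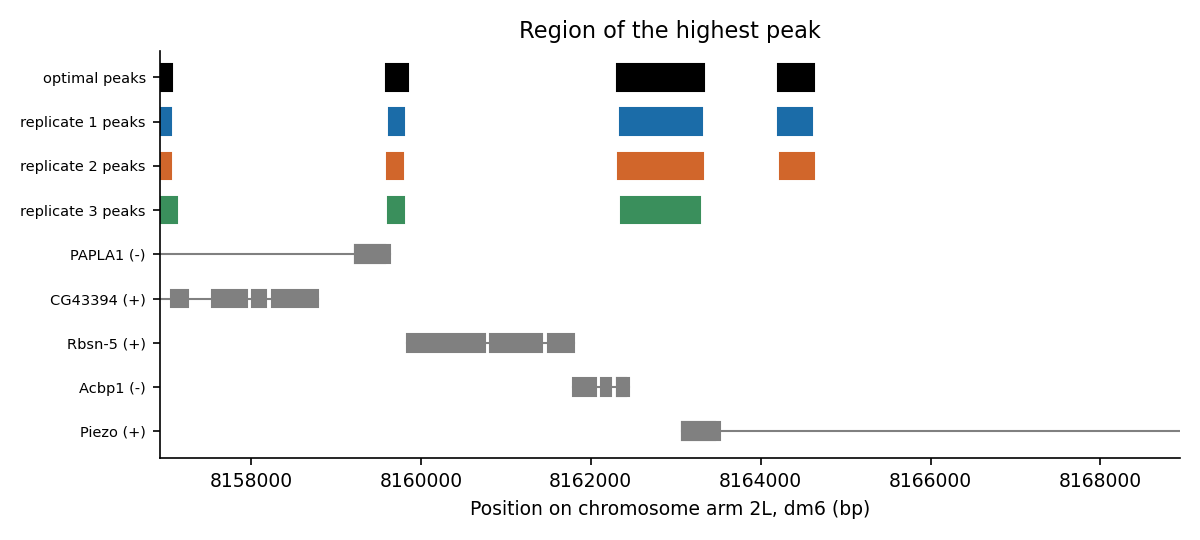
Map of 12000 bp around the highest optimal peak on chromosome arm 2L (horizontal axis, dm6 position in bp; vertical axis, peak lists and genes). Bars are optimal peaks and each replicate's highest-signal peaks, grey boxes are annotated exons on their gene lines with the strand in brackets, and in all 3 replicates the highest peak covers the sequence between the starts of Acbp1 and Piezo.

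The 5 optimal peaks of highest signal that lacked the support of 1 replicate ranked lower, and 3 of them lay in introns. The first ranked 276 (X, 12735464 to 12735672, signal 576.6), in an intron and 4715 bp from the TSS of lncRNA:CR43963. The others ranked 901 or lower and were nearest to lncRNA:CR43626, the mannosidase gene alpha-Man-Ia, lncRNA:CR44156 and lncRNA:CR44854. Replicate 2 had no overlapping candidate at the first 3 of these, and replicate 3 placed the last 2 at ranks 10913 and 5045 of its own list.

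The tagged gene had an optimal peak at its own start. CG4820 (FBgn0037876, 3R, 11216535 to 11217898, plus strand) carried a summit in its 5' UTR, 4 bp from its TSS, with a signal of 109.32 and rank 4407 of 4876. The ribosomal protein gene RpS25 starts next to it on the other strand, and its promoter peak (summit at 11216339) had a signal of 552.3 and rank 299. The peak with its summit nearest to the CG4820 TSS ranked 2739 in replicate 1 (12 bp from the TSS) and 3117 in replicate 2 (8 bp). A stronger replicate 1 peak, rank 204, had its summit at 11216336, by the RpS25 summit, and its end covered 3 bp of CG4820. Replicate 3 had no peak over the gene, and its nearest summit lay 206 bp from the TSS, at the RpS25 peak.

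Binding was concentrated just upstream of gene starts and nearly absent from coding sequence. Summits of 2300 optimal peaks (47.2%, 95% Wilson interval 45.8 to 48.6%) lay within 500 bp of a TSS, 3.53 times the 13.4% ± 0.475 of randomly placed summits (SD over 1000 placements, one-sided permutation p = 0.001, the smallest they can give). Of these, 1921 (83.5%) were upstream of the nearest TSS and 376 downstream, at a median distance of 133 bp. Only 19 summits (0.390%) fell in coding sequence, where random placement gave 17.0%, and 65 (1.33%) fell in 3' UTRs against 4.93%. Summits in 5' UTRs (6.34% against 3.06%), intergenic sequence (42.1% against 30.8%) and introns (47.1% against 42.6%) were more frequent than at random, each with a one-sided permutation p = 0.001. Candidate peaks of the pooled list that overlapped no optimal peak were at promoters in 25.9% of 16046 cases, an odds ratio of 2.56 in favour of the optimal peaks (Fisher's exact test, two-sided, p = 3e-167). The promoter share was 63.2% in the 487 optimal peaks of highest signal and 41.7% in the 487 of lowest signal (odds ratio 2.41, Fisher's exact test, two-sided, p = 2.1e-11).

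Promoters of ribosomal protein genes were bound far more often than those of other genes, and promoters of cuticle protein, chemical receptor, P450 and gut protease genes were rarely or never bound. Across the genome 2770 of 13945 protein-coding genes (19.9%) had an optimal summit within 500 bp of a TSS. Of 24 gene lists tested with Fisher's exact test (two-sided, Benjamini-Hochberg adjustment over the lists), 4 were bound more often than the other genes and 5 less often. The genes of the cytosolic ribosome were bound in 56 of 88 cases (63.6%, 95% Wilson interval 53.2 to 72.9%, odds ratio 7.19, exact test, adjusted p = 8.1e-18). The highest promoter signals in that list were at RpS27 (735.1), RpL7 (562.3), RpS25 (552.3) and RpL32 (474.8). Their signal was ordinary: the median over bound ribosomal protein promoters was 185.7, against 191.8 over all bound promoters.

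Genes for insulator and promoter architecture proteins, which organise chromosome domains and core promoters, were bound in 12 of 21 cases (57.1%, odds ratio 5.40, exact test, adjusted p = 0.00069). Chro had the highest signal there (2107.85), followed by Cp190 (657.5), the promoter-binding factor gene M1BP (371.5) and Trl (346.0), which encodes the GAGA factor. Among genes with a candidate peak at a promoter, this list passed only narrowly (odds ratio 5.07, exact test, adjusted p = 0.046). Polycomb and trithorax group genes, which keep developmental genes off or on, were bound in 11 of 25 cases (44.0%, odds ratio 3.18, exact test, adjusted p = 0.015), with ph-p (2116.17), brm (729.4), E(z) (393.2) and Sfmbt (259.5) leading. Mitochondrial ribosomal protein genes were bound in 29 of 75 cases (38.7%, odds ratio 2.56, exact test, adjusted p = 0.00069), led by mRpL24 (2277.27), mRpS10 (2182.38), mRpL41 (1785.36) and mRpS23 (1579.74). The peaks at mRpL24 and mRpS10 are those named above for the neighbouring genes betaggt-I and Art3. The mitochondrial call ended when each summit was given to its nearest TSS only (odds ratio 1.15), among genes with any candidate peak at a promoter (1.47) and with the 2438 highest-signal peaks (1.95), with exact tests giving adjusted p-values of 0.80, 0.46 and 0.092 and a range from 0.00077 to 0.80 over all alternatives. The Polycomb and trithorax call ended among genes with a candidate peak (1.39, exact test, adjusted p = 0.97) and with the 2438 highest-signal peaks (1.95, adjusted p = 0.43), in a range from 0.0046 to 0.97.

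Cuticle protein genes were bound in 0 of 119 cases, which allows a share of up to 2.52%, and Jonah and trypsin protease genes of the gut in 0 of 27 (up to 11.1%). Odorant, gustatory and ionotropic receptor genes were bound in 1 of 179 cases, Ir60e (signal 122.5; exact test for the list, adjusted p = 5.1e-15). The list of cytochrome P450 genes, drawn by name, had 3 of 85 bound (exact test, adjusted p = 7.9e-05), namely Cyp9f2 (1768.34), Cyp6u1 (561.7) and Cyp1 (135.9). Cyp1 encodes a cyclophilin and not a P450 enzyme. The histone list had 4 of 118 bound (exact test, adjusted p = 1.8e-06). These were His3.3A (434.3), His2Av (316.4) and His3.3B (145.4), which lie outside the tandem histone cluster, and HisCl1 (113.0), which encodes a histamine-gated channel. The gene copies inside the cluster are nearly identical, and how reads that map to several copies were treated is not given in the sources used here. Adjusted p-values of the exact tests were 3.5e-11 for cuticle genes and 0.015 for the proteases. Among genes with any candidate peak, cuticle (odds ratio 0, exact test, adjusted p = 0.051, against 2.7e-10 at the lowest over all alternatives) and P450 genes (odds ratio 0.270, 0.11, against 3.3e-05) no longer passed but stayed below the other genes. The protease call ended with the nearest TSS (exact test, adjusted p = 0.068), with the 2438 highest-signal peaks (0.20) and with peaks that every replicate supports (0.070), in a range from 0.0064 to 0.20, although the odds ratio was 0 in all 3 settings.

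None of the other lists passed. Cell cycle and replication genes were bound in 13 of 38 cases (exact test, adjusted p = 0.094), led by Dp and RnrS (474.5). They passed when summits went to their nearest TSS (exact test, adjusted p = 0.024) or without replicate 1 (0.037), in a range from 0.024 to 1 over all alternatives. Pair-rule and segment polarity genes were bound in 0 of 16 cases (exact test, adjusted p = 0.12) and dosage compensation genes in 0 of 6 (0.84). Aminoacyl-tRNA synthetase genes were bound in 10 of 32 cases, with IleRS at 554.5 and SerRS at 400.7. Proteasome genes were bound in 13 of 48 (Rpn5, 359.0, and Rpt6, 281.1), initiation factor genes in 10 of 44 (eIF6, 1011.74, and eIF4EHP, 708.6) and respiratory complex I genes in 9 of 40 (ND-ASHI, 503.9, and ND-MWFE, 411.9). The count was 3 of 11 in the Enhancer of split complex (E(spl)m3-HLH, 591.8, and E(spl)m7-HLH, 396.6), 5 of 19 for heat shock genes (Hsp27, 922.7, and Hsp83, 276.4) and 5 of 22 for piRNA genes (cuff, 246.5, and piwi, 113.0). Developmental lists gave 2 of 8 Hox genes (Antp, 112.1, and Dfd, 106.1), 1 of 11 gap and maternal genes (bcd, 234.7) and 3 of 16 dorsal-ventral and mesoderm genes (tin, 319.7, and htl, 218.9). Tissue lists gave 4 of 20 muscle genes (Msp300, 493.1, and Tm1, 273.2) and 3 of 18 neural genes (elav, 751.7, and pros, 134.4).

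**Figure D3:**
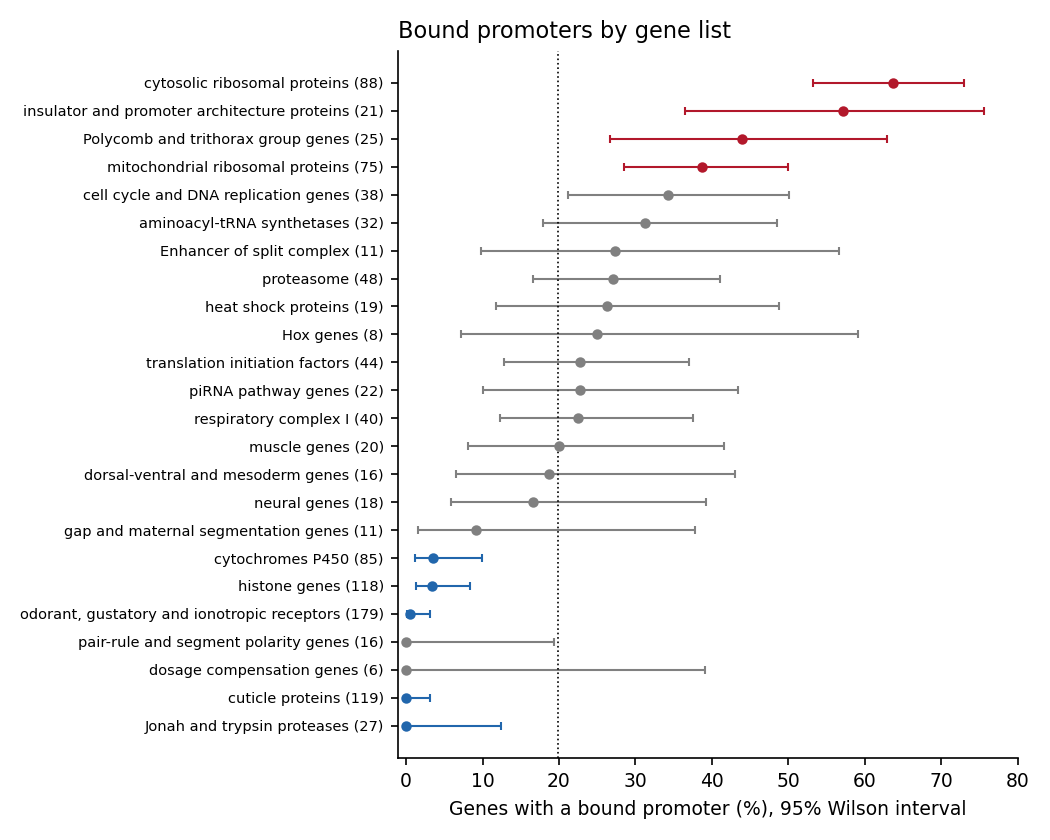
Percent of genes with a bound promoter (horizontal axis) in each of 24 gene lists (vertical axis, number of genes in brackets), with 95% Wilson intervals. Red lists were bound more often and blue lists less often than the other protein-coding genes at an adjusted p under 0.05, grey lists did not pass, and the dotted line is the share over all protein-coding genes, 19.9%.

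Summits carried some short sequences known from insulators and core promoters more often than their flanks did. Of 22 fixed motifs, 9 were more frequent within 50 bp of the summit than in a stretch of the same size split between both flanks at 300 bp, and 5 were less frequent (exact sign test, two-sided, Benjamini-Hochberg adjustment). The core of the CTCF insulator site was at 76 summits and in 14 flanks (1.56% against 0.287%, exact test, adjusted p = 9.8e-11). The DRE element bound by DREF was at 91 summits and in 30 flanks (exact test, adjusted p = 3.6e-08), and core promoter motif 6 at 105 and in 34 (5.6e-09). The homeodomain core TAATTA (503 against 248, exact test, adjusted p = 8.6e-21) and the TATA box (353 against 174, 1.5e-14) contain mostly A and T. The CTCF core passed both at promoters (27 against 6, adjusted p = 0.0014) and away from them (49 against 8, 1.5e-07). The DRE was at 84 promoter summits and 7 others (odds ratio 13.9, Fisher's exact test, two-sided, adjusted p = 4.9e-19). Its flank counts differed the same way, with 27 at promoter peaks and 3 at the others, so promoter sequence held it more often with or without a summit.

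Smaller excesses were seen for the Su(Hw) core (26 against 9, exact test, adjusted p = 0.013), core promoter motif 7 (119 against 82, 0.017), the M1BP motif (31 against 14, 0.027) and the E-box of the Twist type (204 against 163, 0.049). The GAGA repeat was rarer at summits than in flanks (47 against 158, exact test, adjusted p = 8.1e-15), as were the Myc-type E-box (31 against 84, 2.5e-06), CAGCTG (154 against 243, 1.6e-05), the Brinker site (198 against 287, 0.00014) and the Zelda site (19 against 39, 0.019). All of these rarer motifs hold more G and C than A and T, while summit windows were richer in A+T than flanks (67.0% against 55.4%). Base composition as the source of their lower counts was not tested. Nor was it excluded for the more frequent motifs that hold mostly A and T, which include motif 6 and the Twist-type E-box. The Bicoid, STAT, Grainy head, initiator, CRE, AP-1, Pho and BEAF-32 motifs did not pass, although the Bicoid site did without replicate 2 (exact test, adjusted p = 0.013) or 3 (0.038) and the STAT site away from promoters (0.044). The Su(Hw) call was lost when any 1 replicate was left out (exact test, adjusted p of 0.060 to 0.12), that of motif 7 without replicate 1 (0.083) or 2 (0.082), and those of M1BP (0.064) and the Twist-type E-box (0.050, above the limit before rounding) without replicate 1. Over all alternatives the highest adjusted p of the exact test was 0.36 for Su(Hw), 1 for motif 7 and Zelda, 0.98 for M1BP, 0.44 for the Twist-type E-box and the DRE, and 0.16 for Brinker. In a control added after seeing the data, the homeodomain core and motif 6 did not differ detectably from the same sequences read backwards (exact test, adjusted p = 1 and 0.32), and the TATA box was at fewer summits than its reversal (353 against 642, adjusted p = 1.5e-21). CAGCTG (154 against 27, exact test, adjusted p = 9.1e-22) and the Brinker site (198 against 65, 7.6e-17), both rarer at summits than in flanks, were more frequent there than their reversals. By that control the Pho site was also more frequent (60 against 16, exact test, adjusted p = 1e-06) and the Grainy head site less frequent (17 against 57, 7.1e-06). That control counted no reversed motifs in the flanks, and many word pairs passed it at random positions. Its differences therefore cannot be assigned to summits. The DRE call ended with the 2438 highest-signal peaks (exact test, adjusted p = 0.22) and away from promoters (0.44).

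The search for 8-base words without a fixed list returned mainly A/T-rich sequence. Of 6488 words tested on the 2438 odd-ranked peaks, 1069 were more frequent at summits, and 757 of these passed again on the 2438 even-ranked peaks (exact sign test, two-sided, Benjamini-Hochberg adjustment in each part). Of the 757, 742 had 6 or more A or T and 10 had 4 or fewer. The leading word, AAATATAT, was at 176 summits and in 47 flanks of the even-ranked peaks (exact test, adjusted p = 1.2e-16). The A+T content in the summit window was 67.0%, against 55.4% in the flanks. The 10 words richer in G and C included CAACACTG (45 against 7, exact test, adjusted p = 5.5e-07), CACTGAGA (38 against 4, 8.5e-07) and AGATGGCG (33 against 7, 0.00018), part of the CTCF core. These 3 words were chosen after their values were seen. All but AGATGGCG hold ACTG or its complement CAGT, so they are not independent of each other.

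**Figure D4:**
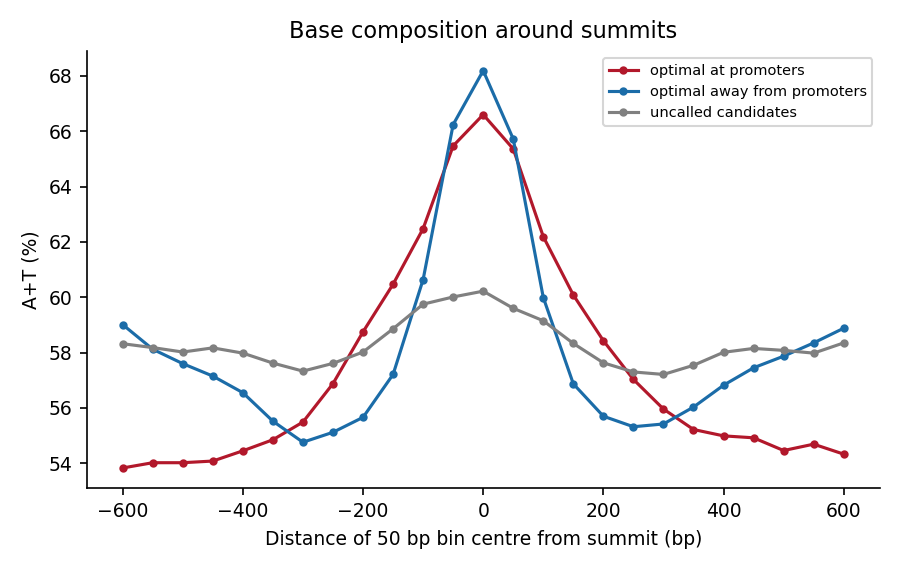
A+T content (vertical axis, percent of bases in bins of 50 bp) against distance from the peak summit (horizontal axis, bp) for optimal peaks at promoters, optimal peaks away from promoters and candidate peaks that were not called. The optimal peaks reach 66.6% and 68.2% at the summit, and the uncalled candidates 60.2%.

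The X chromosome held slightly more optimal peaks than its share of gene starts, a difference that passed under some references and peak sets and not under others. It carried 903 of the 4876 peaks (18.5%, exact 95% interval 17.4 to 19.6%), while 17.0% of protein-coding TSSs lie on it (exact binomial test, two-sided, p = 0.0054). The p of the exact test was 0.0045 against the X share of pooled candidate peaks, 17.0%. It was 0.087 against the X share of the arms' length, 17.6%, 0.085 with the 2438 highest-signal peaks and 0.064 with peaks that every replicate supports. It was 0.15 when support in replicates 1 and 2 was required, leaving out replicate 3 (17.9% on X). Peak density on the large arms ran from 32.8 peaks per Mb on 2R to 38.6 on 2L, with 38.4 on X, while chromosome 4 had 20 peaks, or 14.8 per Mb.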

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

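The dm3 candidate lists hold peaks on chromosomes other than the 6 arms, which entered only the peak counts and overlaps within dm3. Replicate 1 had 108 such peaks of 21610, replicate 2 had 70 of 22796, replicate 3 had 87 of 20917 and the pooled list had 52 of 18434, each above the 3 that a count of 0 allows. Their median signal was lower than that of the whole list, 43.9 against 58.4 in the pooled list. Most lay on the heterochromatin pieces of 3L and 2R, with 21 and 13 in the pooled list, and 1 reached the dm3 optimal list. No explanation of them was tested.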

How the results depend on the processing

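The comparisons with each motif or word read backwards were chosen only after the results were seen. All other alternatives were planned, including the background of genes with a candidate peak, whose use to weigh an explanation below came later. Of the 4876 peaks, 4853 had every replicate behind them with all candidates, 2900 with an overlap of 50% of both peaks and 3174 with summits within 100 bp, and 3838 to 3937 had the other 2 replicates behind them when each was left out. The count was 2421 of the 2438 highest-signal peaks and 3098 of 4205 on dm3. Over the alternatives 36.4 to 57.2% of peaks were at promoters, always above random placement. With 1 replicate left out, the rank correlation is that of the remaining pair. These are the values reported above, 0.790 to 0.835, and no separate check. Of the 24 gene lists, 3 passed against genes with a candidate peak, where the histone, protease, pair-rule, dosage compensation and gap gene lists held too few genes to be tested. The GAGA repeat could not be tested against its reversal. Of the 22 motifs, 9 passed with 25 bp to each side of the summit, 8 with the 2438 highest-signal peaks and 9 away from promoters. Against 757 words in the search reported, 1172 passed with 100 bp to each side and 349 with the 2438 highest-signal peaks. Separate searches gave 396 words of 6 bases and 164 words of 8 bases against their reversals, of which 61 were among the 757. The X share was 18.5% against arm length (p of the exact test 0.087), 18.3% with the 2438 highest-signal peaks, 18.2% with peaks that every replicate supports, and 17.9 to 18.3% leaving out each replicate. The smaller peak sets hold fewer peaks to test; for the others the cause was not tested.

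Direction turned for lists that did not pass in either setting. At 250 bp the odds ratio was 0 for Enhancer of split and Hox genes, 0.601 for muscle and 0.854 for piRNA genes. At 1000 bp it was 0.980 for complex I, 1.54 for dorsal-ventral and 0.844 for muscle genes. With the nearest TSS it was 0.669 for complex I, 1.39 for dorsal-ventral, 1.21 for neural and 0.952 for piRNA genes. Among genes with a candidate peak it was 0.709 for complex I, 0.788 for initiation factors, 0.631 for Hox, 0.965 for cell cycle and 0.788 for piRNA genes. With the 2438 highest-signal peaks it was 0 for Hox, 1.11 for dorsal-ventral and 0.370 for piRNA genes, and with peaks that every replicate supports 0 for Hox, 0.992 for muscle and 0.562 for piRNA genes. Leaving out each replicate gave 0.525 to 0.827 for piRNA, 0.924 to 1.24 for muscle and 0 to 1.65 for Hox genes.

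The summit share minus the flank share, in percentage points, turned for Pho to -0.0205 with 25 bp and -0.431 with 100 bp to each side and -0.246 with the flank at 500 bp. At promoters it was -0.130 for STAT and 0.217 for AP-1, and away from promoters -0.0388 for BEAF-32 and for motif 7 and 0.117 for the initiator. Against the motif read backwards the difference was 2.61 for CAGCTG, -5.93 for TATA, 1.13 for the initiator, -0.0410 for STAT, 0.369 for AP-1, 2.73 for Brinker and -0.779 for Bicoid. Of these, CAGCTG, TATA and Brinker passed in opposite directions in both tests. The cause was not tested. Unknown sequencing depth limits what can be said of peaks that are missing.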

Other observations

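Of the tests in this part, those on highly used gene classes, on genes with candidate peaks, on base composition of all candidates, on core promoters, on base composition as the source of words and on the shares of peaks with the CTCF core were chosen only after the results were seen. Binding was also frequent where 2 genes start close together on opposite strands. Among 5052 protein-coding genes with another protein-coding TSS on the other strand within 1000 bp upstream, 1808 (35.8%) had a bound promoter, against 962 of 8893 other genes (10.8%, odds ratio 4.60, Fisher's exact test, two-sided, p = 9.9e-267). A shared peak counts for both neighbours, but with each summit given to its nearest TSS the shares were 20.8% and 10.5% (odds ratio 2.23, exact test, p = 5e-60). The hypothesis that such promoters are bound more often, written before this test, was met in both forms; gene activity, which was not measured here, may account for it. Bound promoters were counted at 212 of 3261 ncRNA genes (6.50%), 14 of 290 tRNA genes (4.83%), 11 of 269 snoRNA genes (4.09%), 6 of 32 snRNA genes (18.8%) and 0 of 99 rRNA genes, against 19.9% of protein-coding genes, without a test of the difference.

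The excess at ribosomal protein promoters was weighed against 3 technical explanations. Other genes matched within 10% on the sequence lying near their TSSs had a median of 16 bound of 88 over 10000 draws and at most 31, below the 56 observed, which argues against the size of the promoter windows as the cause. Among genes with any candidate peak at a promoter, 56 of 79 ribosomal protein genes were bound (70.9% against 43.9%, odds ratio 3.12, Fisher's exact test, two-sided, p = 1.8e-06), which argues against candidate regions of any kind as the whole cause. A raised signal at all highly used genes stays open. The proteasome, complex I and initiation factor genes together were bound in 24.2% of 132 cases, with an interval of 17.7 to 32.2% that includes the share of all genes. That interval lies below the 53.2 to 72.9% of cytosolic ribosomal protein genes, which argues against a rise of equal size across these lists. The lists were drawn by symbol pattern and hold unbound related genes such as Prosalpha3T, Rpt3R and ND-51L1, whose use was not measured. No expression values or control precipitation are used here. The design holds 1 group, so no biological explanation was tested.

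The A/T-rich summits were weighed against a bias of all candidate peaks and against A/T-rich core promoters. Uncalled candidates rose by 2.76 percentage points of A+T from flank to summit, against 11.6 (95% bootstrap interval 11.2 to 11.9) in optimal peaks, which argues against a bias shared by all candidates as the whole cause. Optimal peaks away from promoters rose by 12.6 points, more than the 10.5 at promoters, which argues against core promoters as the whole cause. A bias that grows with signal stays open, since the rise was 13.8 points in the 487 highest peaks and 9.89 in the 487 lowest. No biological explanation was tested.

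The words enriched at summits were weighed against base composition, base order and properties of any candidate region. Words with 4 or fewer A or T should not rise at A/T-rich summits through composition alone, yet 10 such words passed on both sets of peaks, which argues against composition as their cause. For words with 6 or more A or T composition remains a candidate explanation, and the few words between these groups were not weighed separately. Setting words against themselves read backwards did not settle it. At summits 5.15% of 3184 word pairs passed (interval 4.44 to 5.97%), on either side of the 5% bound set for the test. A pass needed an adjusted p under 0.05 on odd-ranked and again on even-ranked peaks. Pairs of equal frequency, as composition alone gives, would pass less often than that bound, so the bound cannot decide. The pairs that did pass argue against equal frequency for those words, but not for a difference particular to summits. In the flanks 7.29% of 3071 pairs passed, so such differences are also found 300 bp away from the summits. Of the 164 words that passed at summits, 42 also passed in the flanks and 122 did not. Of those 122, 55 were also among the words more frequent at summits than in flanks. The CTCF core was at 98 summits of 16046 uncalled candidates (0.611%), a lower share than the 1.56% of optimal peaks (Fisher's exact test, two-sided, p = 3.8e-09), and in 32 of their flanks (0.199% against 0.287%, p = 0.29). As enrichment over the flank, the ratio was 3.06 in uncalled candidates (interval 2.08 to 4.68) and 5.43 in optimal peaks, whose lower limit was 3.30. By the rule written before the test, an uncalled ratio below that limit, as found, counts against enrichment in any candidate region. The interval of the uncalled ratio, which the rule did not use, includes the limit, so that explanation is left open. No biological explanation was tested.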
